A study of Mus musculus with 12 samples.

How the data were processed

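Poly(A) RNA of 12 samples of mouse embryonic stem cells was selected on oligo(dT), fragmented by chemical hydrolysis and sequenced on a SOLiD 4 instrument, per the labels' protocols. Reads were aligned with Bowtie, per the submitters' processing notes; its version, the genome build and the counting of reads over exons are not given in the sources used here, so no genome coordinates are printed. The deposited values are RPKM (reads scaled to transcript length and to total reads), per the file headers, for 22182 RefSeq transcripts in each of the 12 files, with 1 transcript per gene symbol and symbols and lengths from the authors' deposited table. Reads that near-identical or overlapping genes share, such as the 2-cell-like gene clusters and small RNAs inside host genes, cannot be assigned from these values.

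The values were checked before any test. No value was 0, and values of 0 reads had been replaced by a floor below the value of 1 read. In the serum/LIF libraries 176 to 207 values of short transcripts lay below that floor, against 0 in each 2i and 2i/LIF library. The lowest values of serum/LIF had thus been treated differently, and no label records why. In the 4 unsorted libraries 100% of the low values of short transcripts lay within 0.1 of a whole number of reads, up to 5 reads, and the value of 1 read gave the depth of each (14740000 to 18590000 reads). In the sorted libraries a replicate term had been removed within each culture (serum/LIF and 2i/LIF), a step that no label or header records: among genes with a mean of at least 1 RPKM the summed log2 values of the 2 gates were equal between replicates within 0.001 for 93.1% and 92.9%. Their steps and depth can no longer be read. Deviations of same-numbered HV low and HV high libraries from their group means are opposite by this construction (r = -0.973 and -0.974), so they neither show nor exclude a pairing, and no crossed pairing was fitted. The labels give the replicates numbers and no shared day or culture. No 2 libraries held the same values.

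Groups and replicate numbers were taken from the sample titles. Genes with at least 1 RPKM in 2 or more of the 12 libraries were kept, which left 13925. Fold changes are differences of log2(RPKM + 1), which understate the change of genes with low values. A linear model with the 6 groups and no covariate was fitted to all 12 libraries with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a mean-variance trend) in R 4.3.3, with 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with calls at an adjusted p below 0.05. The contrasts were HV high against HV low in serum/LIF and in 2i/LIF, the difference of these, 2i/LIF against serum/LIF averaged over the gates, and 2i/LIF against 2i in unsorted cells. Because of the removed term, a fit with a replicate term for each sorted culture (4 residual degrees of freedom) was added after the values were seen, and for the culture contrast a test with the spread of the unsorted libraries and 2 replicates per culture. The added replicate terms still give too small a spread for the culture contrast, and for sorted against unsorted cells, which were tested with the spread of the unsorted libraries too. SD is given between the 2 libraries of a group and is too small in the sorted groups for the same reason; SE is the moderated standard error of the log2 fold change.

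The 24 gene lists, written before the data were examined, were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation and on ranks, for lists with at least 5 tested genes, adjusted over the lists within a comparison. Of 591 list entries 578 were found by symbol. Genes are named by a rule of the same date: in each comparison the 10 largest increases and 10 largest decreases among called genes with at least 5 RPKM in the higher group and no overlap between the groups' libraries, with Hhex, Pecam1 and up to 4 genes of smallest p per list described; genes of unnamed models are mostly left unnamed. For the interaction, where the rule did not say what may not overlap, the within-replicate differences of the 2 cultures were used, a choice made after the files were opened. Genes outside the rule (Gata4, and those in the last part of the closing section) were chosen after their values were seen.

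The steps were tested on simulated libraries with the gene means and spreads of these data, 13925 genes, 200 of them changed by 2-fold or 4-fold, and a replicate term added to and then removed from each sorted culture (3 simulations per comparison). For the sort in serum/LIF the designed fit recovered 94.7% of 2-fold and 99.3% of 4-fold changes with 26% false calls, and the fit with replicate terms 90.7% and 99.3% with 7.2%. For the sort in 2i/LIF false calls were 27.5% and 5%, and for LIF in unsorted cells 26.6% and 5.7%. For 2i/LIF against serum/LIF, with a removed replicate term as large as the residual spread, false calls were 92.8% in the designed fit, 77.9% with replicate terms and 23.3% with the spread of the unsorted libraries, which recovered 90.7% of 2-fold and 99.3% of 4-fold changes. Alternatives were other pseudocounts, filters, scalings and variance settings, a replicate block, fits to fewer groups and leaving out each library. Every row of the files is 1 gene symbol, so testing transcripts separately changes nothing.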

Results

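Poly(A) RNA of mouse embryonic stem cells labelled E14, of the 129 background, was sequenced on the SOLiD platform. The cells carried a Hex-Venus reporter, in which the fluorescent protein Venus reports expression of Hhex, a homeobox gene known from the primitive endoderm, the extraembryonic lineage that forms beside the epiblast in the blastocyst. Of the 12 libraries, 8 came from cells sorted into the lowest and highest 25% of reporter fluorescence (HV low and HV high) among live cells positive for the surface protein Pecam1. They had been cultured in serum with leukaemia inhibitory factor (LIF) or in 2i with LIF, where 2i is the MEK inhibitor PD032 at 1 µM with the GSK3 inhibitor CHIR99021 at 3 µM. The other 4 libraries came from unsorted cells in 2i without LIF or in 2i with LIF. Each of the 6 groups had 2 libraries. The unsorted libraries held about 17070000 and 18590000 reads without LIF and 14740000 and 15430000 with LIF, as read from the steps between their low values, so that 1 RPKM of a transcript of the median length of 2469 bases stood for 36.4 to 45.9 reads. The depth of the sorted libraries is unknown. Between 12584 and 13306 genes reached 1 RPKM in a library, and 13925 genes were tested.

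The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries. The sorted values had been centred before they were deposited. For 93.1% of genes in serum/LIF and 92.9% in 2i/LIF, the summed log2 values of HV low and HV high were equal in replicates 1 and 2 within 0.001, against 0.396% in the unsorted libraries. A difference between replicate 1 and replicate 2 had thus been taken out of each sorted culture. Removing such a term does not alter the differences between HV high and HV low within a replicate, but whether the unrecorded step did more than this cannot be seen in the values. The spread between replicates is understated, and a fit with a replicate block within each sorted culture, which counts the removed term, is given beside the designed fit.

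Transcripts of the sorted reporter's own gene did not follow the gates. Hhex measured 2.05 ± 0.56 RPKM in the libraries labelled HV low and 2.47 ± 0.68 in those labelled HV high in serum/LIF (SD, n = 2), and 2.17 ± 0.45 and 1.44 ± 0.3 in 2i/LIF, with adjusted p of 0.808 and 0.277. In serum/LIF it was 2.95 RPKM in HV high against 1.65 in HV low of replicate 1, and 2.00 against 2.45 in replicate 2. In 2i/LIF it was lower in the library labelled HV high of both replicates. The unsorted libraries held 1.94 ± 0.23 RPKM in 2i and 1.95 ± 0.73 in 2i with LIF. Pecam1, the gene of the gating antigen, lay between 37.2 and 48.8 RPKM in every library. Directions between the gates are therefore those of the labels.

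**Figure D1:**
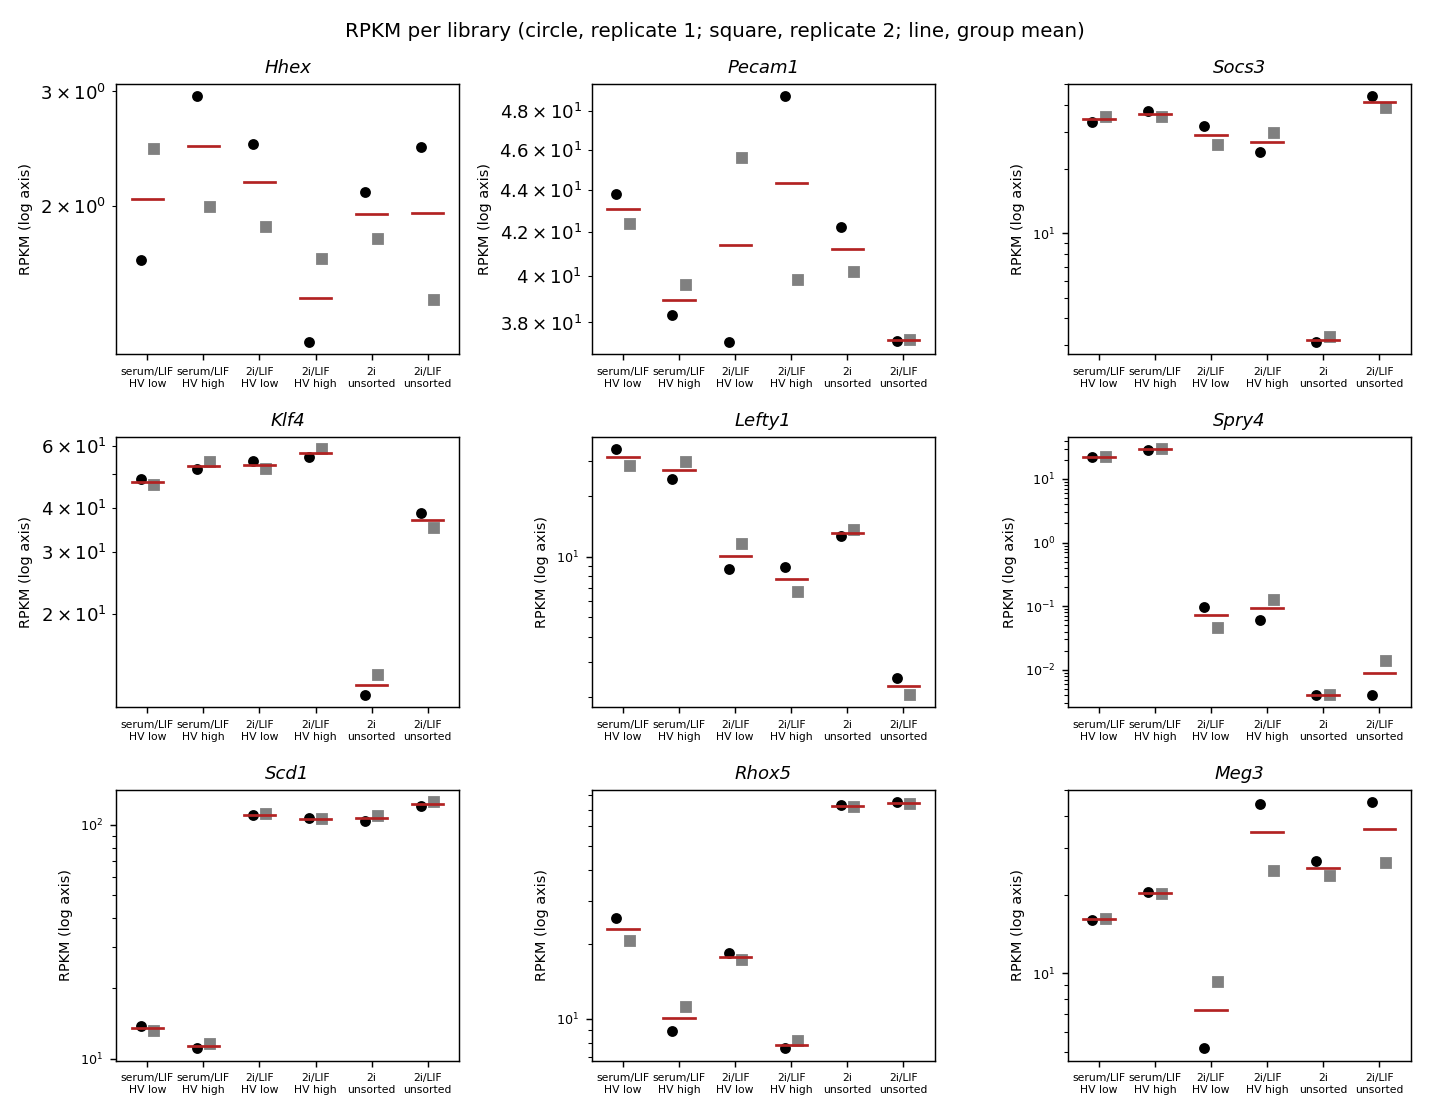
RPKM on a log axis for 9 named genes in the 12 libraries, with a circle for replicate 1, a square for replicate 2 and a red line for the mean of each of the 6 groups. Hhex stays between 1.23 and 2.95 RPKM in all libraries, Socs3 is 3.10 and 3.27 RPKM in the 2i libraries without LIF against 44 and 38.6 with LIF, and Spry4 is 22 to 29.5 RPKM in serum/LIF and at most 0.126 in 2i.

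The first comparison asked which transcripts differ between the reporter fractions in serum/LIF. Rhox5, an X-linked homeobox gene, measured 23.1 ± 3.6 RPKM in HV low and 10 ± 1.5 in HV high (log2 fold change -1.12 ± 0.11 SE), and Dppa3, a germline and preimplantation gene, 7.68 ± 1.5 and 2.9 ± 0.57 (log2 fold change -1.15 ± 0.14). Plac8 measured 9 ± 1.4 and 4.62 ± 0.73 RPKM. In the other direction, Hmga2, an architectural chromatin protein, measured 3.96 ± 0.41 and 6.54 ± 0.67 RPKM, the mitotic kinase gene Aurka 40.6 ± 2.5 and 55.4 ± 3.4, and Lars2, the mitochondrial leucyl-tRNA synthetase, 479 ± 56 and 814 ± 96. The sterol and lipid synthesis list had a median log2 fold change of -0.16, with 27 of its 29 tested genes below 0, as with Srebf2, the regulator of sterol synthesis, at 43.5 ± 0.67 RPKM in HV low and 36.3 ± 0.56 in HV high. The epithelial list (median -0.25, 6 of 6 genes below 0) held Cldn6 at 23.2 ± 3.6 and 15.6 ± 2.4 RPKM, and the trophoblast list had a median of -0.10. The 21 tested primitive endoderm genes had a median of -0.02, with 0 of them called, and 0 of them when adjusted over the list alone.

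None of these genes passed once the removed replicate term was counted. In the designed limma fit 6 genes were higher and 19 lower in HV high at an adjusted p below 0.05, among 1601 at an unadjusted p below 0.05. With the replicate block within each sorted culture limma called 0 genes, with 705 at an unadjusted p below 0.05 where chance gives 696, and the lowest adjusted p was 0.133. Without any 1 of the 4 libraries 0 or 1 gene was called. In limma's camera test of lists with a preset correlation, the sterol list had an adjusted p of 9.79e-07, the epithelial list 0.00554 and the trophoblast list 0.0121. With an estimated correlation these were adjusted p = 0.534, 0.482 and 0.482, so that no list passed. Adjusted over the list alone, 5 sterol genes, 2 epithelial genes and 2 trophoblast genes were lower in HV high in the designed fit.

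The same question in 2i/LIF gave more calls, and the differences were wider in replicate 1 alone. Their SD over 9210 genes with a mean of at least 5 RPKM was 0.383 in replicate 1 and 0.2 in replicate 2, against 0.206 and 0.181 in serum/LIF. Rhox5 measured 17.8 ± 0.84 RPKM in HV low and 7.84 ± 0.37 in HV high (log2 fold change -1.09 ± 0.11), Lefty2, an inhibitor of Nodal signalling, 25.4 ± 1.1 and 11.7 ± 0.49 (log2 fold change -1.05 ± 0.11), Trh 19.4 ± 10 and 5.84 ± 3, and Trpm1 17.5 ± 4.7 and 8.36 ± 2.2. Gadd45a and Slc23a1 were also among the genes with lower values in HV high. The non-coding RNAs Meg3 and Rian of the imprinted Dlk1-Dio3 region measured 7.24 ± 2.9 and 5.68 ± 2.2 RPKM in HV low and 34.5 ± 14 and 27.7 ± 11 in HV high (log2 fold changes 2.10 ± 0.32 and 2.09 ± 0.26). The paternally expressed Peg10 measured 4.51 ± 1.2 and 11.2 ± 3 RPKM. Of 22 tested imprinted genes, 9 were higher and 0 lower in HV high in the designed fit, with the same 9 higher and 2 lower when adjusted over the list alone. Tcstv1, a gene of the 2-cell-like state, measured 0.916 and 2.47 RPKM in the HV low libraries and 11.1 and 4.14 in the HV high libraries, and 14 of the 16 tested genes of that list lay above 0 (median 1.28). Genes of serine and amino acid synthesis lay lower in HV high (15 of 19, median -0.20), such as Psat1 at 244 ± 1.4 and 197 ± 1.1 RPKM and Phgdh at 77.7 ± 0.019 and 62.7 ± 0.016. The primitive endoderm list had a median of -0.09, with Srgn at 2.46 ± 0.038 and 4.36 ± 0.067 RPKM and Col4a1 at 1.98 ± 0.82 and 4.71 ± 1.9 RPKM, and 2 of its 21 genes higher (4 higher and 3 lower adjusted over the list alone).

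In all, the designed fit called 583 genes higher and 283 lower in HV high in 2i/LIF, and limma called 0 with the replicate block within each sorted culture, where 2291 genes had an unadjusted p below 0.05 and the lowest adjusted p was 0.148. With replicate number as a single replicate block over all 12 libraries it called 102. The count was 0 without replicate 1 of either gate, 525 without HV low replicate 2 and 1178 without HV high replicate 2. The share of called genes that were higher fell from 67.3% to 55.6% with median-ratio scaling and to 48.4% with quantile normalization. By camera with the preset correlation, the serine and amino acid list (adjusted p = 1.04e-05), the Myc and ribosome biogenesis list (median -0.10), the histone list (median -0.15) and the germline, glycolysis, 2-cell-like and imprinted lists (medians 0.36, 0.23, 1.28 and 0.33) passed. With an estimated correlation the serine and amino acid list alone passed, at an adjusted p of 0.0366, which became 0.128 with the replicate block. The Myc list had adjusted p = 0.052 with an estimated correlation, and the other 5 lists each had adjusted p = 0.62.

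The sort differences correlated weakly between replicates and between cultures. Across the 13925 tested genes, which are not independent replicates, the difference between HV high and HV low of replicate 1 correlated with that of replicate 2 at r = 0.12 in serum/LIF and r = 0.101 in 2i/LIF, whereas the difference made by LIF in the unsorted cells gave r = 0.597. The fitted sort effects of the 2 cultures, which share no library, correlated at r = 0.02, with 1 gene called higher in both where 0.251 is expected by chance and 2 called lower in both where 0.386 is expected, while 6 were called in opposite directions where 0.917 are expected. The sort effect in 2i/LIF and the LIF effect in unsorted cells correlated at r = -0.0386. With so little agreement between replicates of the sort, these low correlations do not show that the underlying effects differ. The interaction of sort and culture called 53 genes in the designed limma fit. For 41 of them the signed log2 fold change of HV high against HV low was higher in 2i/LIF than in serum/LIF. This is not always the larger difference in size. Gm11686, 1 of the 41, measured 50.1 RPKM in HV low and 10.4 in HV high in serum/LIF, and 38.3 and 41.6 in 2i/LIF. With the replicate block within each sorted culture the interaction called 0 genes, and the lowest adjusted p was 0.165 (2715 and 1372 genes at an unadjusted p below 0.05 in the 2 fits). Without any 1 of the 8 sorted libraries 0 to 2 genes were called, except without 2i/LIF HV high replicate 2, where 55 were. Dppa3 was among the 53, with 10.7 ± 0.37 RPKM in HV low and 13.5 ± 0.47 in HV high in 2i/LIF against the lower HV high value in serum/LIF.

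The comparison of 2i/LIF with serum/LIF, averaged over both gates, asked how the sorted cells differ between the media when LIF is present throughout. The media differ in serum as well as in the inhibitors, so no difference can be put to the inhibitors alone. The serum/LIF libraries also differ from those in 2i/LIF in the floor of their lowest values. A processing step particular to 1 culture cannot be told apart from the medium. Targets of the ERK pathway fell. Spry4, a feedback inhibitor of the pathway, measured 22.2 ± 0.29 and 29.2 ± 0.38 RPKM in HV low and HV high in serum/LIF and 0.0725 ± 0.037 and 0.093 ± 0.047 in 2i/LIF (log2 fold change -4.61 ± 0.05 SE, adjusted p = 7.85e-11; SE 0.11 and adjusted p = 6.88e-05 with the spread of the unsorted libraries). The ETS factor gene Etv4 fell from 20.9 ± 1.3 and 25.5 ± 1.6 RPKM to 0.578 ± 0.0085 and 0.442 ± 0.0064, and the ERK phosphatase gene Dusp6 from 13.4 ± 0.83 and 15.1 ± 0.93 to 1.16 ± 0.076 and 0.607 ± 0.04. Of 23 tested ERK targets, 16 fell and 1 rose (median log2 fold change -0.60). Sterol and lipid synthesis genes rose, 29 of 29 with a median of 1.12. The stearoyl-CoA desaturase genes Scd1 and Scd2 rose from 13.5 ± 0.45 and 54.6 ± 0.89 RPKM in HV low serum/LIF libraries to 111 ± 0.44 and 262 ± 39 in HV low 2i/LIF libraries, and Fdps, of the mevalonate pathway, from 53.7 ± 2.7 to 164 ± 19.

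Genes of the postimplantation epiblast fell (13 of 18, with 1 higher), among them the DNA methylation genes Dnmt3l, from 194 ± 3.5 to 23.7 ± 5.7 RPKM in HV low, and Dnmt3b, from 15.7 ± 1.5 to 4.99 ± 0.34. The maintenance cofactor Uhrf1 rose (log2 fold change 0.53 ± 0.04, SE 0.06 with the spread of the unsorted libraries). Of 17 genes shared by naive and primed pluripotency 16 fell, with a median of -0.45, including Utf1 (130 ± 7.6 to 10.8 ± 0.65 RPKM in HV low), Lin28a (71.7 ± 1.2 to 22.9 ± 1.5) and Zic3. The naive list went both ways, with 11 genes higher and 8 lower of 24: Zfp42 fell by 0.87 and Jam2 rose by 0.57 on the log2 scale. In the imprinted list 12 of 22 fell, Peg10 and Mest the most, and 2 rose. Peg10 measured 40 to 51 RPKM in serum/LIF and 3.65 to 13.3 in sorted 2i/LIF, but 37.7 and 32 in unsorted 2i/LIF. Most of its fall was thus absent from unsorted cells of that medium. By the spread of the unsorted libraries, 11 of the 22 imprinted genes were lower and 3 higher in sorted than in unsorted 2i/LIF. Of 16 genes of the 2-cell-like state 15 fell, such as Zscan4b, whose near-identical copies share reads. Of 12 Wnt targets, Axin2 (log2 fold change 1.79 ± 0.11), Cdx1 (2.43 ± 0.13) and Tnfrsf19 (1.49 ± 0.10), with SE of 0.18, 0.21 and 0.12 by the spread of the unsorted libraries, were among 6 that rose, while Bmp4 was among 3 that fell. Cdx1 measured 0.392 to 0.561 RPKM in serum/LIF and 5.03 to 9.56 in sorted 2i/LIF, but 0.623 and 0.855 in unsorted 2i/LIF. For Axin2 these were 1.67 to 2.2, 7.92 to 10.5, and 3.11 and 3.5. Tnfrsf19 kept its rise in unsorted 2i/LIF, at 4.48 ± 0.32 RPKM. Trpm1, Spic, Crxos1, Ap3b2 and Dmgdh also ranked among the 10 largest increases, with log2 fold changes of 2.08 to 3.09. Gja1, Spink3, S100a6, Id1 and Enpp3 ranked among the 10 largest decreases, at -2.81 to -3.46. In the primitive endoderm list the designed fit called 8 genes higher and 6 lower of 21, and 3 higher and 4 lower with the spread of the unsorted libraries. Adjusted over the list alone, 29 sterol genes rose, and 16 ERK targets, 14 postimplantation, 17 shared pluripotency, 15 2-cell-like and 12 imprinted genes fell.

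The designed limma fit called 4192 genes higher and 3393 lower in 2i/LIF, and 184 and 301 of them changed at least 2-fold. The share that was higher, 55.3%, was 49.2% with median-ratio scaling, so the larger side depends on the scaling. These counts rest on a spread from which the variation between replicates had been removed, and in simulated libraries of that kind with no culture effect the designed fit called 2510 of 13925 genes on average, 18.3 of them at 2-fold or more. With the spread of the unsorted libraries and 2 replicates per culture, an alternative chosen after seeing the data, 2131 genes were higher and 1757 lower. The size of the removed term is unknown, and with that spread 2 times as large 87 were higher and 82 lower, among them Spry4, Etv4, Dusp6, Dnmt3l and 17 of 29 sterol genes, but 5 of 23 ERK targets, 4 of 18 postimplantation, 4 of 17 shared pluripotency, 3 of 16 2-cell-like and 2 of 22 imprinted genes lower, and not Uhrf1, Axin2, Cdx1, Zfp42 or Jam2. With the spread as measured the counts within the lists were 29 of 29 sterol genes higher and 15 of 23 ERK targets, 14 of 18 postimplantation and 14 of 17 shared pluripotency genes lower. By camera with the preset correlation the sterol list (adjusted p = 5.64e-17), the shared pluripotency, ERK, postimplantation, 2-cell-like, imprinted, epithelial (median -0.63) and serine lists (median 0.21) passed, and with an estimated correlation the ERK list alone, at an adjusted p of 0.0355, against 0.107 with the replicate block. The sterol, shared pluripotency and postimplantation lists then had adjusted p = 0.198, 0.0505 and 0.198, and the 2-cell-like, imprinted, epithelial and serine lists adjusted p = 0.476, 0.25, 0.343 and 0.198. All these camera tests used the centred spread, which is too small for this contrast. None was run with the spread of the unsorted libraries.

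**Figure D2:**
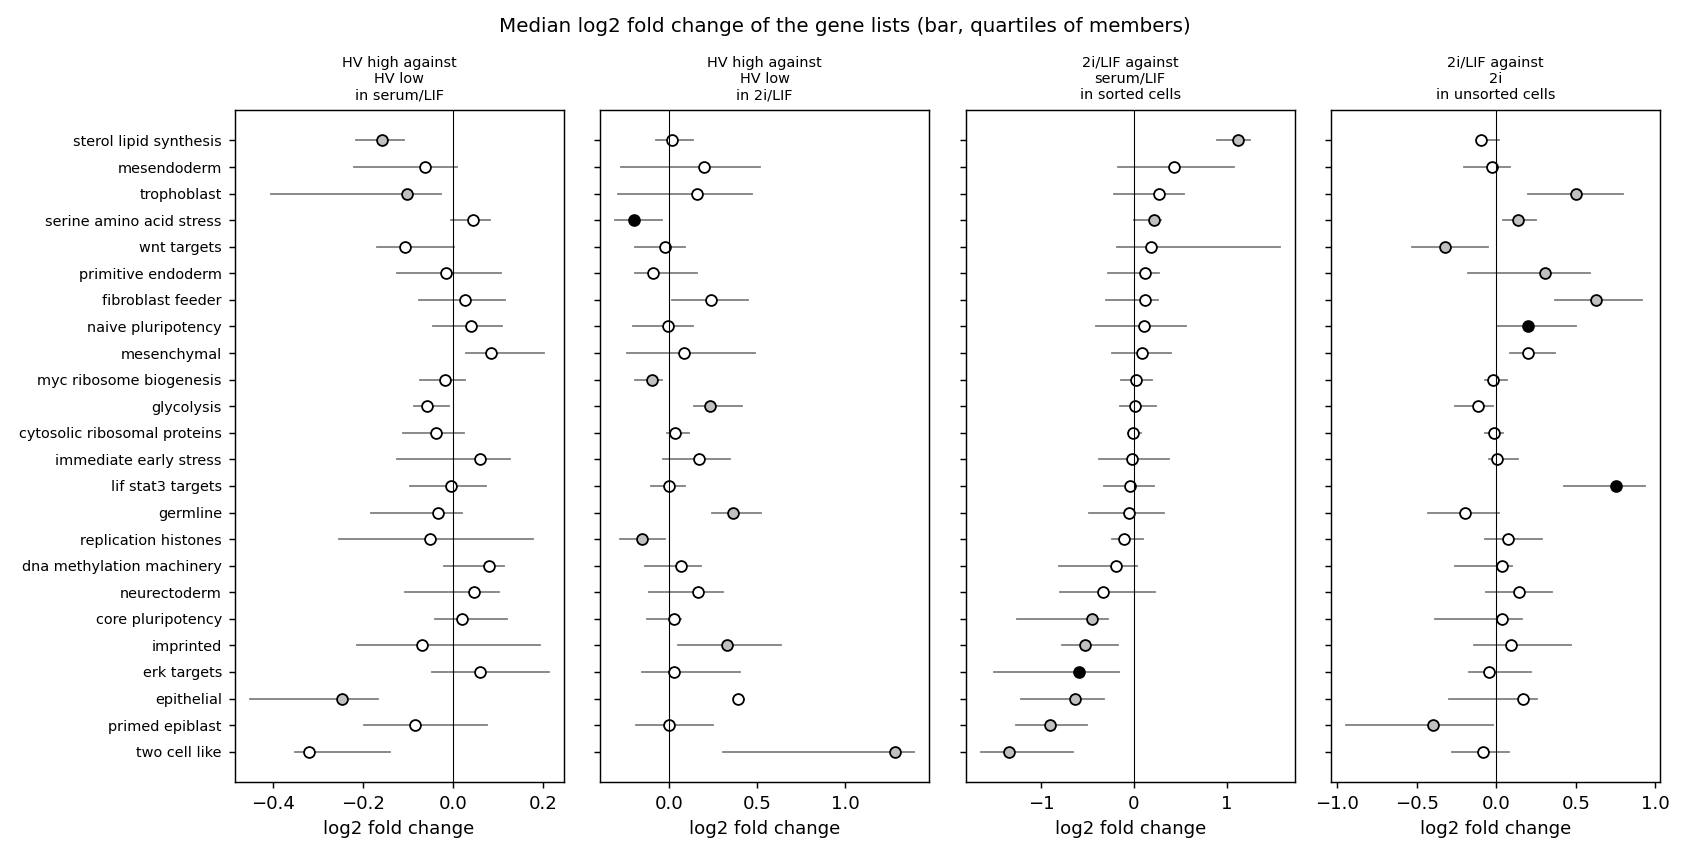
Median log2 fold change (point) and quartiles (bar) of the tested members of 24 gene lists in 4 comparisons, from the designed fit. Grey points passed camera with the preset correlation, black points also with an estimated correlation, and white points neither. The sterol and lipid synthesis list has a median of 1.12 in 2i/LIF against serum/LIF, and the LIF and STAT3 list a median of 0.75 in 2i/LIF against 2i.

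The last comparison asked what LIF adds to 2i in unsorted cells. Socs3, the feedback inhibitor of LIF receptor signalling, rose from 3.19 ± 0.12 to 41.3 ± 3.8 RPKM (SD, n = 2; log2 fold change 3.33 ± 0.12 SE, adjusted p = 4.31e-06), and the pluripotency factor gene Klf4 from 12.6 ± 1.2 to 36.9 ± 2.5. Of 26 tested LIF and STAT3 targets 18 rose and 1 fell (20 and 1 adjusted over the list alone), including Tgm2 (1.53 ± 0.091 to 10.1 ± 1.6 RPKM), Bcl3 and Pim3. In the naive list 9 of 24 rose and 1 fell: Tbx3 rose from 13.3 ± 0.81 to 26.7 ± 4.2 RPKM and Fgf4 from 87.8 ± 0.58 to 132 ± 12, and Manba fell. Postimplantation genes fell, 9 of 18 with 2 higher, such as the Nodal antagonists Lefty1 (13.1 ± 0.63 to 2.27 ± 0.31 RPKM) and Lefty2 (20 ± 0.68 to 8.65 ± 1.2), the neural and epiblast factor Zic2 (21.2 ± 2.3 to 7.74 ± 0.16) and the methyltransferase gene Dnmt3a (6.22 ± 0.064 to 2.81 ± 0.097). Of 12 Wnt targets 4 fell and 1 rose, with Notum falling from 9.73 ± 0.14 to 5.58 ± 0.096 RPKM.

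Extraembryonic genes were among those that rose with LIF. Of 23 tested trophoblast genes 10 rose and 1 fell (13 and 2 adjusted over the list alone), with the keratin genes Krt18 from 6.66 ± 0.25 to 18.9 ± 1.1 RPKM and Krt19 from 4.27 ± 1.7 to 13.1 ± 0.87, and Tead4 from 2.97 ± 0.0064 to 5.73 ± 0.28. Of 21 primitive endoderm genes 6 rose and 3 fell (10 and 3 adjusted over the list alone). The basement membrane genes Lama1 and Nid1 rose from 8.32 ± 1.1 and 48.4 ± 1 RPKM to 21.7 ± 1.9 and 78.9 ± 6.3, and Emb fell from 16.9 ± 2.1 to 7.04 ± 0.25. Gata4, the endoderm transcription factor gene, was low throughout, at 0.836 and 0.592 RPKM in 2i and 1.11 and 1.34 in 2i with LIF. In the fibroblast list 8 of 15 rose and 0 fell, with Vim from 53.5 ± 3.8 to 105 ± 2.6 RPKM, Tagln from 2.51 ± 0.25 to 7.59 ± 1 and Col1a1 from 0.568 ± 0.077 to 3.48 ± 0.77. Ly6g6e, Krt42, Bhmt, Glod5, Ly6a, Serpinb1a and Krt8 were also among the 10 largest increases, and Enox1, Ina, Pdzd4, Tcea3 and Enpp3 among the 10 largest decreases. The small nucleolar RNA entries Snord57 and Snora34 ranked there too, Snord57 with both LIF libraries at the value of 0 reads.

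The designed fit called 957 genes higher and 749 lower with LIF. With the replicate block within each sorted culture, which lowers the residual degrees of freedom from 6 to 4, limma called 310 and 151. Apart from Gata4, which lay outside the naming rule, every gene given with a fold or RPKM change in these 2 accounts of LIF passed there too. A fit to the 4 unsorted libraries alone called 657 genes, and leaving out a 2i replicate gave 791 or 1023. In the replicate block fit 12 LIF and STAT3 targets rose and 0 fell, 5 trophoblast and 5 fibroblast genes rose and 0 fell, and 4 postimplantation genes fell and 1 rose. By camera with the preset correlation the LIF and STAT3 list had an adjusted p of 1.13e-15, and the fibroblast (median 0.62), trophoblast (0.50), naive (0.20), postimplantation (-0.40), serine (0.14), Wnt (-0.32) and primitive endoderm lists (0.31) passed as well. With an estimated correlation the LIF and STAT3 list and the naive list passed, both at an adjusted p of 0.0433 (0.0977 with the replicate block), and the trophoblast, fibroblast, postimplantation and primitive endoderm lists had adjusted p = 0.111, 0.13, 0.261 and 0.228. For the serine and Wnt lists it was adjusted p = 0.0908 and 0.13.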

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

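The tests on the correlation between replicates were chosen after the result was seen. The interaction of sort and culture, a planned test, set apart 53 genes, and the sort difference in 2i/LIF minus that in serum/LIF was 2.71 on the log2 scale for Mir18, 1.46 for Dppa3, 1.31 for Plac8, 1.30 for Rny3, 1.12 for Rac3, 1.02 for Akr1b10, 0.97 for Sdc4 and 0.81 for Copz2. It was -0.81 for Hmga2, -0.72 for Gtf3c6, -0.61 for Mrpl52, -0.60 for Ddah1, -0.54 for Ccnb1ip1 and -0.39 for Tmem126a. Among genes of unnamed models it was 2.29 for Gm11686, 1.47 for Gm3167, -0.86 for Gm6211, -0.74 for Gm11189, -0.71 for LOC100039155 and -0.56 for Gm13152. None of them passed the limma fit with the replicate block within each sorted culture. Mir18 and Rny3 are short entries that can take reads of longer transcripts.

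The same test on gene lists with camera's preset correlation set apart the 2-cell-like list (median difference 1.61), the epithelial (0.69), imprinted (0.44), germline (0.40), glycolysis (0.28) and sterol lists (0.18), and, with the opposite sign, the serine and amino acid (-0.24) and Myc and ribosome lists (-0.10). With an estimated correlation the serine and amino acid list alone passed, at an adjusted p of 0.0229, which became 0.0941 with the replicate block. The Myc and epithelial lists then had adjusted p = 0.22 and 0.269, the imprinted list 0.478, the sterol list 0.598 and the 2-cell-like, germline and glycolysis lists each 0.54.

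The weak agreement of the sort differences between replicates was weighed against 2 technical explanations. Too few reads per gene would let the correlation rise among abundant genes. Among 1828 genes with a mean of at least 50 RPKM it was 0.161 in serum/LIF and 0.159 in 2i/LIF, against 0.12 and 0.101 over all genes, with bootstrap standard errors of 0.0484 and 0.0294. The rise was within 2 standard errors and the depth of the sorted libraries is unknown, so this explanation stays open. Gate labels exchanged in 1 replicate would make the correlation negative, and the lower of the 2 was 0.101 with a bootstrap standard error of 0.0143 over genes. Genes are not independent, so this error does not measure the spread between replicates. Labels exchanged in both replicates of a culture would leave the correlation unchanged, and this was not tested. A small transcript difference between the gates, or a sort that differed between the replicates, stays open and was not tested. In 2i/LIF the SD of the difference between gates was 0.383 in replicate 1 and 0.2 in replicate 2, over 9210 genes with a mean of at least 5 RPKM.

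Of the 35 splits of the 8 sorted libraries into 4 and 4, 1 gave as many genes as the split by culture, which was that split itself, with 6373 genes in a fit with 2 groups, and the highest of the other splits called 1 gene. The splits do not decide about chance, because the libraries of each culture had been centred on each other, which shrinks the spread for the split by culture alone. With the spread of the unsorted libraries 3888 genes were called, against 6.3 on average in simulated libraries with no culture effect under the same test. This argues against chance as far as the sorted cultures varied between replicates like the unsorted ones, which the centred values no longer show. The simulated genes also varied independently of each other. A difference between cultures shared by many genes is thus not counted in the 6.3.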

How the results depend on the processing

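The replicate block within each sorted culture and the spread of the unsorted libraries, as it is and widened, were chosen after the result was seen; the other settings were planned. No named gene or list that was called in the designed fit or in the changed one reversed its direction in any setting. For genes, most settings could not have reversed it. The replicate blocks, variance settings, filters, fits to fewer groups and spreads of the unsorted libraries leave a gene's fold change as it was. Outside the interaction, genes named for the largest changes had no overlap between the groups' libraries, so leaving out a library could not reverse them. For these the absence of reversals does not measure stability. Changes of sign among uncalled genes and lists were not counted.

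With the replicate block within each sorted culture limma called 0 genes between the gates in serum/LIF (705 at an unadjusted p below 0.05), 0 in 2i/LIF (2291), 0 for the interaction (1372) and 461 for LIF in 2i, and 39 named genes passed, of 93 in the designed fit. With a replicate block by the number of the labels these were 0, 102, 0 and, for named genes, 47. The culture comparison called 3888 genes with the spread of the unsorted libraries, and 1045, 169 and 2 with that spread 1.5, 2 and 3 times as large.

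Fitting only the groups of a comparison gave 0 genes for each sort, 159 for the interaction, 657 for LIF and 56 named genes. Without a filter on low values the sort in serum/LIF gave 163 genes and the interaction 328. With a mean of at least 5 RPKM the sorts gave 5 and 497 genes and the interaction 23, and without a variance trend the interaction gave 102. At 2-fold or more the counts were 6 and 34 for the sorts, 17 for the interaction, 485 for the culture comparison and 116 for LIF. With camera's correlation estimated, 5 of 120 pairs of list and comparison were called, against 34 with the preset one.

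Leaving out 1 library at a time gave 0 to 1 genes for the sort in serum/LIF, 0 to 1178 for that in 2i/LIF, 0 to 55 for the interaction, 791 to 1377 for LIF and 44 to 80 named genes. The correlation of the 2 sort effects, 0.0197 in the designed fit, lay between 0.0049 and 0.0382, and was -0.0055 with a pseudocount of 0.1 and 0.0688 with the stricter filter. That of the LIF effect and the sort effect in 2i/LIF, -0.0386, lay between -0.0531 and -0.011, and was -0.0759 with the stricter filter.

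Scaling moved the share of called genes that were higher. For the interaction it was 77.4%, 67.2% with median-ratio scaling and 61.8% with quantile normalization, and for the sort in serum/LIF 24% and, with quantile normalization, 5.26%. The median shift in log2 fold change was at most 0.065 in size.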

Other observations

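All tests in this part were chosen after the results were seen. Sorted and unsorted cells of the same medium, 2i/LIF, differed in many genes: 2166 were higher and 1573 lower in the sorted libraries with the spread of the unsorted libraries and 2 replicates each. With the replicate block within each sorted culture limma called 2443 and 1758, from a spread that centring had made too small. Dppa3 lay between 10.5 and 13.9 RPKM in the 4 sorted 2i/LIF libraries and at 139 and 169 in the unsorted ones (log2 fold change -3.56, adjusted p = 0.000163 with the spread of the unsorted libraries), and Rhox5 between 7.58 and 18.4 against 74.9 and 73.4. The Wnt targets Cdx1 and Axin2 were higher in the sorted libraries, Cdx1 at 5.03 to 9.56 RPKM against 0.623 and 0.855, but of the 12 tested Wnt targets 3 were higher and 1 lower by the spread of the unsorted libraries, and the list had an adjusted p of 0.801 by camera. The histone list, whose transcripts mostly lack poly(A) tails, had a median of -0.39 in sorted against unsorted libraries, with 8 of 27 genes lower by the spread of the unsorted libraries, and an adjusted p of 0.000225 by camera with the preset correlation and 0.365 with an estimated one.

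Genes that differed between 2i/LIF and serum/LIF overlapped with those that changed with LIF in 2i, in comparisons that share no library. In the designed fits 478 genes were higher in both, where 288 are expected of independent lists, and 373 lower in both, where 183 are expected, and 389 changed in opposite directions, where 459 are expected. The correlation across 13925 genes was r = 0.181. Independent lists are a loose reference, because both contrasts come from 1 fit and share each gene's spread. For the 2i/LIF sort and LIF, at r = -0.0386, the counts also exceeded it. There 68 genes were higher in both against 40.1 expected, 27 lower against 15.2, and 91 opposite against 50.8. The culture calls also rest on a spread that is too small. In the overlap of culture and LIF, Enpp3 and Mest show the lower side and Crxos1 and Ly6a the higher one. In the imprinted Dlk1-Dio3 region, Meg3, Rian and Mirg moved together in the sorted 2i/LIF libraries: HV low replicate 1 held 5.18, 4.15 and 0.293 RPKM, HV low replicate 2 held 9.29, 7.21 and 0.562, HV high replicate 1 held 44.3, 35.1 and 3.15, and HV high replicate 2 held 24.7, 20.2 and 1.65. In the serum/LIF libraries they stayed within 16 to 20.4, 16.9 to 19.5 and 1.32 to 1.83. Centring ties the values of a gene together across the gates and replicates of a culture, so these libraries are not independent observations. The wider gap in replicate 1 of 2i/LIF was general, with an SD of the gate difference of 0.383 against 0.2 in replicate 2 over 9210 genes.

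Fos, Egr1 and Fosb, genes induced within minutes by handling or growth factors, were higher in sorted than in unsorted 2i/LIF libraries. Fos lay between 9.80 and 30.4 RPKM in the sorted 2i/LIF libraries and between 19.3 and 25.7 in serum/LIF, against 0.804 and 1 in the unsorted ones, and Egr1 between 7.37 and 21.8 against 0.11 and 0.042. Handling during the sort could raise such genes, but the median of the 19 tested genes of the immediate early and stress list was 0.089 with an estimated-correlation p of 0.387, so the list does not decide it. Less complete inhibition of ERK in the sorted cultures would return its other targets toward their serum/LIF values as well. Of the log2 gap between serum/LIF and unsorted 2i/LIF, the sorted 2i/LIF libraries made up a share of 0.752 to 1.079 for Fos, Egr1 and Fosb. For 11 other ERK targets, at least 2-fold higher in serum/LIF than in 2i, the median share was 0.027 (SD 0.272) and the highest 0.516. This argues against less complete inhibition as far as these targets report it. All serum/LIF libraries came from sorted cells, so the gap includes any effect of the sort common to both media. Fos, Egr1 and Fosb had also been picked because they rose, so their shares are no independent reference. Spry4 measured 0.046 to 0.126 RPKM in sorted 2i/LIF, against 0.004 and 0.014 in unsorted 2i/LIF and 22 to 29.5 in serum/LIF. The shares were taken on log2(RPKM + 1), which flattens values below 1 RPKM. They therefore do not exclude a small rise of targets as low as Spry4. A brief return of ERK activity during handling was not tested. A batch between sorted and unsorted libraries, with 3730 genes outside the list called by the spread of the unsorted libraries, cannot be told apart from the sort, since the labels name no batch that sorted and unsorted libraries share.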
